A study of Mus musculus with 71 samples.

How the data were processed

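The series holds 71 samples in 34 groups of mouse oocytes and oocyte-like cells, and 68 of them in 33 groups were used. The labels of the other 3, oocytes of primordial follicles, match no column by name, so they were left out with the 2 of 29 planned comparisons that needed them. GV oocytes were matched by the stage in their column names. A further 80 columns of the table belong to no sample of the series and were not used.

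Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with STAR 2.6.0 and counted with featureCounts 1.6.0. The values deposited are TPM, transcript counts scaled for length and to the same total in each library, with 1 value per gene symbol and library. How reads that fit several copies of a gene were counted is not stated. Levels of near-identical families (Oas1, Oog, Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Nlrp4) are therefore uncertain. The table used here ends within a row: of 15163 rows the incomplete last one and 22 whose names read as dates were dropped, which left 15140 genes. Of these 14555 matched a gene name of GENCODE M21 (GRCm38), nearly all on chromosomes 1 to 5 and 10 to 19, and 585 did not. Genes elsewhere, 7 of the 19 targeted ones among them, were not analysed here. Depth is not recorded in TPM, so no precision from counting can be given. The genes present took a share of 0.521 to 0.708 of the TPM total of a library.

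Changes were computed on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with the trend and robust options, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. Adding 1 to TPM understates the changes of genes with low values. In vitro oocytes were fitted together (42 libraries, 21 groups, 21 residual degrees of freedom), and DIOLs and GV oocytes together (26 libraries, 12 groups, 14 residual degrees of freedom). Sharing the spread across all groups of a fit was needed because most groups hold 2 libraries. Genes with TPM of at least 1 in at least 2 libraries of a fit were tested, 12306 in the first and 11603 in the second. A gene was called at an adjusted p under 0.05 and an absolute log2 change of at least 1. Groups, comparisons and alternatives, apart from those named as added, were chosen at the same time as the gene lists.

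Of 22 gene lists 20 were tested with camera, a limma test of whether a list moves against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 540 tests. Mitochondrially encoded transcripts and ribosomal proteins had fewer than 3 members among the genes used and were not tested. With the preset correlation 184 tests passed, and 115 of these passed with a correlation estimated from the data as well. Members called were counted over all genes tested, and adjusted over the list alone, which stands beside the count where it differed.

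Genes named in the text are the targeted genes, the called genes with the largest changes, called list members and a fixed set of levels. The second kind had replicate values that did not overlap between groups and a mean TPM of at least 10 in the higher group. From them the 10 highest and 10 lowest were taken for comparisons with at least 300 calls, 5 and 5 for those with at least 50, and 2 and 2 for the rest, leaving out names of predicted genes and pseudogenes. Of each list up to 4 called members with the largest change were eligible, and of lists with no call 2 with the highest level. Examples of genes called in opposite directions in 2 knockouts, the copied genes and replicate values shown for the Sohlh1 knockout and DIOLs.S of day 7, and the levels of targets in other knockouts, were chosen after their values were seen. Positions are those of GENCODE M21.

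The steps were tested on simulated data. With 100 genes changed by a log2 of 1.5 in simulated data for the Hes6 knockout comparison (12291 genes), 90% were called, and 100% of those changed by 3. For the GV comparison (11568 genes) both were 100%, and limma called 0 unchanged genes in either.

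Alternatives were a pseudocount of 0.1, no filter, the replicate number as a block, TPM rescaled by the median of ratios, 1 fit over all samples, each library left out in turn, an estimated correlation for lists, a higher TPM limit for similarity and no fold threshold for overlaps. A fit without the Sohlh1 knockout libraries and one without genes of shared sequence were added after seeing the data. Shared sequence was taken as the percent of a gene's transcript sequence found in another annotated gene of GENCODE M21, and its limits of 20 and 5% were set after seeing the data. Overlaps were set beside 20 simulated draws of unchanged groups against the same controls.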

Results

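RNA was measured in mouse oocytes made in culture and in oocytes grown in the animal, as polyA-selected, directional sequencing libraries given in TPM, which scale each library to the same total. The in vitro oocytes came from embryonic stem cells of a C57BL/6 x 129 background that carry the germ cell reporters Blimp1-Venus and Stella-CFP. Germ cell-like cells made from them were joined with female gonadal somatic cells of embryonic day 12.5 into reconstituted ovaries, and oocytes positive for Stella-CFP (SC) were sorted by flow cytometry on day 11 or day 13 of differentiation. This sort, which selects cells by the germ cell reporter, would remove most somatic cells. Wild-type oocytes of both days and 19 knockouts, 4 taken on day 11 and 15 on day 13, made up 21 groups and 42 libraries. A further 12 groups and 26 libraries held directly induced oocyte-like cells (DIOLs), matured DIOLs and germinal vesicle (GV) oocytes from the animal. DIOLs came from a stem cell line named MGA8 induced with Shield1, a compound that stabilises proteins carrying a destabilising domain. The labels do not name the introduced genes, so levels of the screened factors in DIOLs are not split into own and introduced copies, and they do not say what the S in DIOLs.S denotes. Each group had n = 2 libraries, apart from the competent and incompetent GV oocytes with n = 3 each. Depth is unknown, because TPM keep no read totals. Each library showed between 8011 and 10596 genes at 1 TPM or more. Replicates correlated across genes at r between 0.956 and 0.998, apart from the Sohlh1 knockout at 0.843. Levels are means ± SD over the libraries of a group and log2 changes, on log2(TPM + 1), are given ± SE. A gene rose or fell where the adjusted p was under 0.05 and the log2 change at least 1. Gene lists were fixed before the data were examined and tested against all other genes, and where a list passed but not with a correlation estimated from the data, that adjusted p stands beside the main one. P-values measure only the spread between these libraries, since the labels do not say whether replicates are separate cultures.

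Targeted genes were examined in their own knockouts to check the labels. Sohlh1, a transcription factor of early oocytes (chromosome 2, 25842995 to 25847248, GRCm38), went from 909 ± 2.47 TPM (n = 2) to 5.18 and 0 in the knockout libraries (adjusted p = 7.3e-15). Dynll1, a light chain of the dynein motor (chromosome 5, 115297110 to 115300999), fell from 413 ± 16.5 to 22.9 ± 2.29 TPM (log2 change -4.11 ± 0.093, adjusted p = 2.5e-22). Lhx8, a homeobox factor of primordial oocytes (chromosome 3, 154306294 to 154330659), fell from 331 ± 61.9 to 45.7 ± 2.93 TPM (log2 change -2.82 ± 0.12, adjusted p = 2.5e-16). Kdm1b, a histone demethylase of growing oocytes (chromosome 13, 47043499 to 47085279), fell from 1008 ± 23.1 to 198 ± 19.4 TPM (log2 change -2.35 ± 0.12, adjusted p = 7.7e-13). Stat3, the signal-dependent transcription factor (chromosome 11, 100885098 to 100939540), fell from 319 ± 13.6 to 71.3 ± 3.79 TPM (log2 change -2.15 ± 0.077, adjusted p = 8.7e-18). Tbpl2, an oocyte paralog of the TATA-binding protein (chromosome 2, 24071721 to 24096595), fell from 211 ± 1.51 to 65.2 ± 7.65 TPM (log2 change -1.69 ± 0.49, adjusted p = 0.0056). That call ended with a pseudocount of 0.1 (adjusted p = 0.078). Hes6 (chromosome 1, 91411483 to 91414038) fell from 150.2 ± 2.38 to 50.6 ± 2.37 TPM (log2 change -1.55 ± 0.17, adjusted p = 3.2e-06). Levels of 3 targets were lower with an adjusted p under 0.05 but a log2 change under 1: Sfr1, a partner of recombination proteins, at -0.92 ± 0.098 (adjusted p = 1.4e-06, and a log2 change of -1.04 after rescaling), Thap7 at -0.75 ± 0.20 (adjusted p = 0.023) and Sub1, a transcriptional coactivator, at -0.49 ± 0.087 (adjusted p = 5.3e-05). Ell3, an elongation factor of RNA polymerase, read 105 ± 10.6 TPM v 305 ± 23.5 in wild type and did not pass (log2 change -1.54 ± 0.39, adjusted p = 0.074). It passed without the Sohlh1 knockout libraries (adjusted p = 3.1e-05) and with 1 fit over all samples (adjusted p = 0.018). Ccnk, cyclin K, read 171 ± 10.5 TPM v 168 ± 5.64 (log2 change 0.020 ± 0.090, adjusted p = 0.95), so these are called the libraries labelled Ccnk knockout throughout. Sohlh1, Dynll1, Stat3, Hes6, Thap7 and Sfr1 were lower in their own knockout than in the 18 others. The lowest other was near for Hes6 (69.8 TPM), Stat3 (91.8), Thap7 (115) and Sfr1 (495). Tbpl2 and Ell3 were lower in 7 others each, Lhx8 and Kdm1b in 5, Sub1 in 4 and Ccnk in 3. A lower level does not identify these knockouts. Lhx8 read 27.4 ± 6.73 TPM in the Figla and Tbpl2 3.50 ± 1.36 in the Nobox knockout. Sub1 read 330.2 ± 20.4 TPM in its own libraries, 319.7 ± 3.29 in the Stat3 and 318 ± 29.2 in the Figla knockout of the same day, so these are called the libraries labelled Sub1 knockout. Figla, Nobox, Ybx3, Foxr1, Mef2b, Tcf25 and Noto were not analysed, so their labels are unchecked.

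**Figure D1:**
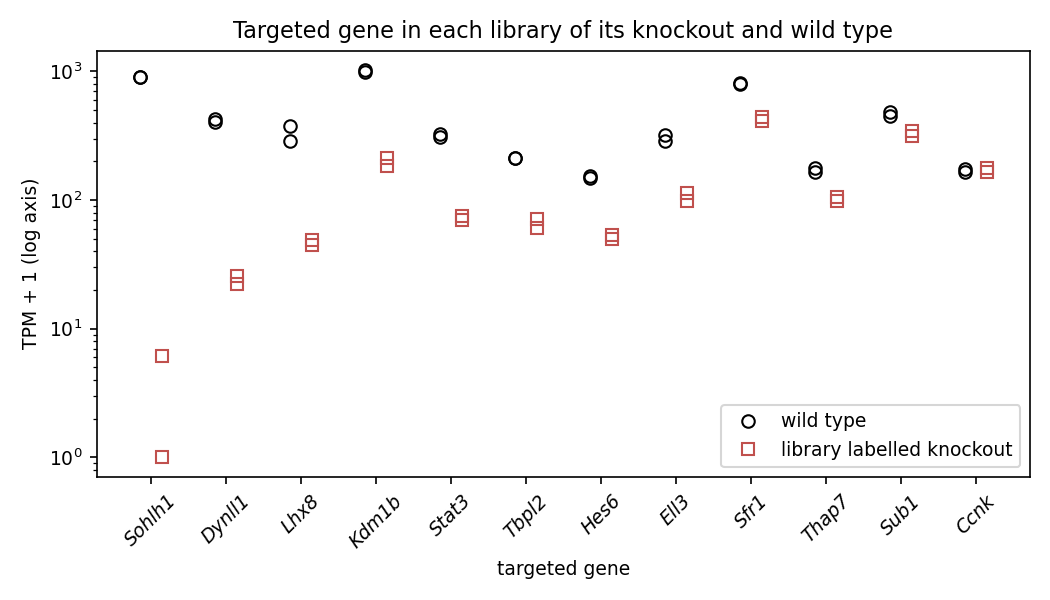
Level of each targeted gene in its own knockout and in wild type of the same day, as TPM + 1 on a log axis. Circles are wild-type libraries and squares are libraries labelled knockout, and Ccnk is the target whose libraries overlap with wild type around 171 ± 10.5 TPM.

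Wild-type libraries of day 13 were compared with those of day 11. Genes of the egg coat and of oocyte secretion rose together: 9 of 9 measured members rose (adjusted p = 8.7e-10). Zp3, a glycoprotein of the zona pellucida, rose from 1893 ± 70.6 to 16324 ± 139 TPM (log2 change 3.11 ± 0.11, adjusted p = 2.5e-17). Oosp1, an oocyte-secreted protein, rose from 29.6 ± 7.50 to 669 ± 34.3 TPM (log2 change 4.48 ± 0.54, adjusted p = 2.5e-07). In the subcortical maternal complex list 4 of 4 measured members rose (adjusted p = 2.3e-07), with Padi6 going from 4191 ± 75.8 to 28907 ± 629 TPM. Growing-oocyte transcripts rose too (12 of 17 measured members rose and 5 were not called, or 15 rose after rescaling; adjusted p = 3.8e-15). Maternal mRNA storage genes rose as well (5 of 11 measured members rose and 6 were not called; adjusted p = 7.0e-08). Zar1, a maternal mRNA-binding protein, went from 53.0 ± 8.63 to 1495 ± 59.9 TPM. Of 21 measured granulosa and gonadal somatic markers 16 fell and 5 were not called (adjusted p = 1.2e-06). Whether less somatic cell RNA on day 13 caused this was not tested. Amhr2, the receptor of anti-Müllerian hormone, fell from 316 ± 3.44 to 5.36 ± 1.77 TPM (log2 change -5.67 ± 0.16, adjusted p = 2.4e-19). Inha, the inhibin alpha chain, went from 293 ± 2.47 to 12.6 ± 1.24 TPM. Hsd3b1, an enzyme of steroid synthesis, went from 86.4 ± 15.5 to 0.265 ± 0.276 TPM and Myl9, a myosin light chain, from 428 ± 0.891 to 1.29 ± 0.707. In the early meiosis list 7 of 16 measured members fell and 9 were not called (adjusted p = 0.025, and adjusted p = 0.40 with an estimated correlation, adjusted p = 0.091 after rescaling). Rec8, the meiotic cohesin, went from 13.6 ± 0.361 to 0.610 ± 0.467 TPM (adjusted p = 0.065 without wild-type day 13 replicate 1). In the immediate early and heat shock list 2 of 14 measured members rose, 8 fell and 4 were not called, or 2 rose and 9 fell adjusted over the list alone (adjusted p = 0.0033, and adjusted p = 0.21 with an estimated correlation). Jun went from 651 ± 1.17 to 20.8 ± 0.714 TPM. Across all genes 2707 of 12306 were called, 677 higher and 2030 lower. The libraries differed in scale by -0.39 on log2, and relative to it 1112 were higher and 1396 lower.

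The Lhx8 knockout of day 11 was set against wild type of the same day. Zp3 fell from 1893 ± 70.6 to 14.6 ± 0.686 TPM (log2 change -6.92 ± 0.11, adjusted p = 3.2e-25), Padi6 from 4191 ± 75.8 to 31.5 ± 5.54 TPM and Npm2, an oocyte histone chaperone, from 760.0 ± 64.0 to 5.67 ± 4.95 TPM (n = 2). In the egg coat list 8 of 9 measured members fell and 1 was not called, or 9 fell adjusted over the list alone (adjusted p = 1.8e-08). In the subcortical maternal complex list 4 of 4 measured members fell (adjusted p = 4.7e-09). In the growing-oocyte list 11 of 17 measured members fell and 6 were not called (adjusted p = 4.8e-10). Screened factors fell with them (6 of 12 measured members fell and 6 were not called; adjusted p = 1.3e-07, or 5 of 11 and adjusted p = 2.8e-06 without Lhx8 itself): Tbpl2 went from 65.6 ± 2.05 TPM to 0 in both libraries and Ell3 from 134 ± 13.9 to 7.15 ± 3.31. Early meiosis genes rose: 12 of 16 measured members rose and 4 were not called, or 14 rose adjusted over the list alone (adjusted p = 1.2e-09). Dmc1, the meiotic recombinase, rose from 16.7 ± 4.96 to 430.2 ± 15.4 TPM (log2 change 4.63 ± 0.31, adjusted p = 3.5e-12). Prdm9, which marks sites of recombination, went from 22.4 ± 5.70 to 278 ± 10.1 TPM. Midkine (Mdk), a secreted growth factor, went from 5.79 ± 4.79 to 347 ± 8.15 TPM. Blood and immune markers were higher too (5 of 10 measured members rose and 5 were not called, or 7 rose adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.41 with an estimated correlation). C1qa, a complement protein of macrophages, was listed at 0 in both wild-type libraries and at 42.3 ± 5.55 TPM in the knockout. The pluripotency gene Pou5f1 went from 383 ± 13.2 to 30.4 ± 0.184 TPM. DNA methylation genes fell (3 of 9 measured members fell and 6 were not called; adjusted p = 0.0016). The comparison called 2690 genes, 1525 higher and 1165 lower.

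In the Figla knockout of day 11, whose target is a basic helix-loop-helix factor of oocytes, Zp3 fell from 1893 ± 70.6 to 1.51 ± 0.651 TPM (log2 change -9.58 ± 0.11, adjusted p = 8.6e-29) and Gdf9, an oocyte growth factor, from 424 ± 33.9 to 0.690 ± 0.0990 TPM (n = 2). Egg coat genes fell (8 of 9 measured members fell and 1 was not called, or 9 fell adjusted over the list alone; adjusted p = 1.3e-09). Among growing-oocyte transcripts 1 of 17 measured members rose, 12 fell and 4 were not called (adjusted p = 2.6e-12). Screened factors were lower: 6 of 12 measured members fell and 6 were not called (adjusted p = 2.5e-07). Sohlh1 went from 1171 ± 65.8 to 19.0 ± 11.8 TPM and Lhx8 at 331 ± 61.9 to 27.4 ± 6.73. Early meiosis genes rose (14 of 16 measured members rose and 2 were not called, or 11 rose after rescaling; adjusted p = 6.1e-08). Spo11, which makes the meiotic DNA breaks, went from 12.3 ± 4.16 to 207 ± 22.0 TPM. Stromal markers did not pass as a list (8 of 16 measured members rose and 8 were not called; adjusted p = 0.090). Pecam1, of endothelium, nevertheless went from 1.98 ± 0.191 to 72.5 ± 18.3 TPM and Col1a1, a collagen, from 6.32 ± 0.0566 to 111 ± 4.38. Blood and immune markers did not pass either (6 of 10 measured members rose and 4 were not called, or 7 rose adjusted over the list alone; adjusted p = 0.10). Lyz2, the lysozyme of macrophages, was at 197 ± 7.64 TPM. Among the highest calls were housekeeping genes with copies in the genome: Hmgn2, a chromatin protein, went from 8.65 ± 4.61 to 289 ± 26.1 TPM, and Erh was listed at 0 in both wild-type libraries and at 45.1 ± 1.42. Genes that share at least 20% of their sequence with another gene had a median log2 change 0.48 above that of genes sharing under 5%, against -0.21 to 0.050 in the 17 knockouts other than Figla and Sohlh1. In all 3457 genes were called, 2285 higher and 1172 lower, and relative to a difference in scale of 0.24 they were 1635 and 1456. The pattern was seen in the Sohlh1 knockout of day 13 and in DIOLs as well, which are not labelled as knockouts: Hmgn2 averaged 115 to 735 TPM in their 9 groups before maturation, and 15.6 in matured DIOLs. High values of such genes thus occur without loss of Figla, although DIOLs differ in cell type too. No wild-type in vitro library shows them, so what the loss adds for genes with copies stays open.

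The Stat3 knockout of day 11 asks what this signalling factor does in oocyte growth. Zp3 fell from 1893 ± 70.6 to 10.8 ± 1.22 TPM (log2 change -7.33 ± 0.11, adjusted p = 7.6e-26), Padi6 from 4191 ± 75.8 to 29.4 ± 5.27 TPM and Gdf9 from 424 ± 33.9 to 3.45 ± 1.53 TPM (n = 2). In the egg coat list 8 of 9 measured members fell and 1 was not called, or 9 fell adjusted over the list alone (adjusted p = 7.9e-08). In the growing-oocyte list 1 of 17 measured members rose, 12 fell and 4 were not called (adjusted p = 8.7e-10). Early meiosis genes rose: 12 of 16 measured members rose and 4 were not called (adjusted p = 9.7e-08). Dmc1 went from 16.7 ± 4.96 to 412 ± 17.2 TPM and Hormad2, of the meiotic chromosome axis, from 25.9 ± 12.5 to 300.3 ± 20.2. Dmrt1, a gonadal transcription factor, rose from 4.12 ± 1.79 to 382 ± 2.83 TPM (log2 change 6.27 ± 0.32, adjusted p = 8.6e-15). Top2a, the topoisomerase of dividing cells, went from 43.5 ± 7.03 to 503 ± 5.60 TPM. In the cell cycle list 6 of 18 measured members rose, 4 fell and 8 were not called (adjusted p = 0.66). Among germline specification genes 4 of 8 measured members rose, 2 fell and 2 were not called (adjusted p = 0.52). Dazl, an RNA-binding protein of germ cells, went from 425 ± 46.1 to 1675 ± 80.3 TPM and the receptor gene Kit from 475 ± 27.7 to 142 ± 2.97. Of 3360 called genes 1947 were higher and 1413 lower, and 1590 and 1587 relative to a difference in scale of 0.13.

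Macrophage genes stood at the top of the libraries labelled Sub1 knockout of day 11, in which Sub1 was no lower than in the Stat3 and Figla knockouts. Spp1, osteopontin, rose from 2.82 ± 1.75 to 1423 ± 58.1 TPM (log2 change 8.62 ± 1.55, adjusted p = 6.3e-05). Ctss, a lysosomal protease, was listed at 0 in both wild-type libraries and at 251 ± 10.9 TPM in these libraries, and C1qa at 0 and 126 ± 19.6 TPM (n = 2). Blood and immune markers rose (7 of 10 measured members rose and 3 were not called; adjusted p = 0.0012, and adjusted p = 0.19 with an estimated correlation). In the granulosa list 1 of 21 measured members rose, 6 fell and 14 were not called (adjusted p = 0.076). Oocyte genes fell: in the egg coat list 7 of 9 measured members fell and 2 were not called, or 8 fell adjusted over the list alone (adjusted p = 8.0e-07). In the subcortical maternal complex list 4 of 4 measured members fell (adjusted p = 1.1e-07). Zp3 fell from 1893 ± 70.6 to 55.4 ± 5.85 TPM (log2 change -5.07 ± 0.11, adjusted p = 8.0e-22), Padi6 from 4191 ± 75.8 to 197 ± 5.97 TPM, and Sohlh1 from 1171 ± 65.8 to 342 ± 13.1 TPM (adjusted p = 0.12 with a pseudocount of 0.1). Early meiosis genes rose (11 of 16 measured members rose and 5 were not called, or 12 rose adjusted over the list alone; adjusted p = 2.1e-08). Msh5, of meiotic crossovers, went from 19.1 ± 0.467 to 177 ± 28.3 TPM. Calls numbered 2800, 1661 higher and 1139 lower.

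In the Nobox knockout of day 13, of a homeobox factor of early follicles, Npm2 fell from 5249.6 ± 70.1 to 5.07 ± 4.37 TPM (log2 change -9.97 ± 0.38, adjusted p = 3.5e-17), Gdf9 from 1936 ± 56.3 to 6.12 ± 0.0141 TPM and Zar1 from 1495 ± 59.9 to 0.520 ± 0.184 TPM (n = 2). Egg coat genes fell (9 of 9 measured members fell; adjusted p = 1.5e-11). Among growing-oocyte transcripts 16 of 17 measured members fell and 1 was not called (adjusted p = 2.5e-23). Pou5f1 fell from 702 ± 2.38 to 4.76 ± 0.919 TPM (log2 change -6.94 ± 0.098, adjusted p = 1.2e-26). Rec8 rose from 0.610 ± 0.467 to 257 ± 14.5 TPM (log2 change 7.35 ± 0.95, adjusted p = 3.2e-07). In the early meiosis list 12 of 16 measured members rose and 4 were not called, or 8 rose after rescaling (adjusted p = 5.4e-04, and adjusted p = 0.18 with an estimated correlation). Granulosa markers were higher (16 of 21 measured members rose, 2 fell and 3 were not called; adjusted p = 0.023). Krt18, a keratin of epithelia, went from 0.190 ± 0.0141 to 177 ± 5.04 TPM and Inha from 12.6 ± 1.24 to 341 ± 8.96. Immediate early genes were higher as well (11 of 14 measured members rose, 1 fell and 2 were not called; adjusted p = 9.7e-04, and adjusted p = 0.16 with an estimated correlation). Fos went from 32.1 ± 6.60 to 682 ± 11.5 TPM. In the p53 list 8 of 16 measured members rose and 8 were not called (adjusted p = 0.095). Cdkn1a, an inhibitor of cell division, went from 8.80 ± 1.68 to 185 ± 11.2 TPM. Gsn, an actin-severing protein, rose from 1.03 ± 1.02 to 348 ± 4.99 TPM. The 4738 calls were 3692 higher and 1046 lower, and 2368 and 1618 relative to a difference in scale of 0.52.

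The Sohlh1 knockout of day 13 listed 3 oocyte genes at 0 in both libraries (n = 2): Zar1, at 1495 ± 59.9 TPM in wild type, Lhx8, at 459 ± 6.75, and Tbpl2, at 211 ± 1.51. Egg coat genes fell (9 of 9 measured members fell; adjusted p = 8.7e-10). In the growing-oocyte list 15 of 17 measured members fell and 2 were not called (adjusted p = 3.5e-14). Npm2 fell from 5249.6 ± 70.1 to 12.8 ± 0.863 TPM (log2 change -8.58 ± 0.38, adjusted p = 7.2e-16). DNA methylation and imprint genes fell (1 of 9 measured members rose, 5 fell and 3 were not called; adjusted p = 0.0026). Zfp57, a guard of imprints, went from 588 ± 6.09 to 61.9 ± 9.27 TPM. Genes of piRNA production, which silences transposons, were lower (7 of 16 measured members fell and 9 were not called; adjusted p = 3.2e-04, and adjusted p = 0.15 with an estimated correlation). Tdrd9 went from 138 ± 9.92 to 24.4 ± 2.68 TPM. The early meiosis list did not pass (6 of 16 measured members rose and 10 were not called; adjusted p = 0.10), although Hormad1 rose from 8.53 ± 3.12 to 89.8 ± 3.01 TPM. Its replicates stood apart in stromal and immune genes: Lyz2 read 2.71 and 921 TPM, Col1a1 20.6 and 372 and Dcn, a matrix proteoglycan, 61.1 and 869.7, while the globin gene Hba-a1 was alike at 80.2 and 89.0. Stromal markers were higher (11 of 16 measured members rose, 1 fell and 4 were not called; adjusted p = 0.039, and adjusted p = 0.50 with an estimated correlation). Blood and immune markers were higher as well (7 of 10 measured members rose and 3 were not called; adjusted p = 0.036, and adjusted p = 0.41 with an estimated correlation). Genes with shared sequence stood 0.64 above the others in median log2 change, and Atp5g2, a mitochondrial gene with copies, went from 1.51 ± 1.52 to 373 ± 26.0 TPM. Atp5g2 averaged 174 TPM in the Figla knockout, 77.8 to 156 in the 9 groups of DIOLs before maturation, 5.17 in matured DIOLs and at most 7.78 in the 19 other in vitro groups. Of 4391 called genes 2748 were higher and 1643 lower (2203 and 2098 relative to a difference in scale of 0.30). As in the Figla knockout, loss and library set were not separated in these calls.

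Without Tbpl2 on day 13, oocyte genes were lower but still measurable: Padi6 fell from 28907 ± 629 to 6529.7 ± 3.49 TPM (log2 change -2.15 ± 0.12, adjusted p = 1.9e-13), Zp1 from 4129 ± 72.2 to 468 ± 41.9 TPM and Zar1 from 1495 ± 59.9 to 144 ± 29.2 TPM (n = 2). In the egg coat list 9 of 9 measured members fell (adjusted p = 1.4e-08). In the maternal mRNA storage list 6 of 11 measured members fell and 5 were not called (adjusted p = 6.4e-09). Pabpc1l, a poly(A)-binding protein of oocytes, fell from 139 ± 11.1 to 6.46 ± 0.445 TPM (log2 change -4.23 ± 0.29, adjusted p = 5.9e-12). Early meiosis genes rose (12 of 16 measured members rose and 4 were not called, or 13 rose adjusted over the list alone; adjusted p = 9.3e-08). Dmc1 went from 3.98 ± 3.08 to 226 ± 38.1 TPM and Rec8 from 0.610 ± 0.467 to 68.4 ± 0.453. Granulosa markers rose too (16 of 21 measured members rose and 5 were not called; adjusted p = 2.7e-04). Amhr2 went from 5.36 ± 1.77 to 185 ± 17.4 TPM and Amh, anti-Müllerian hormone, at 1.10 ± 0.134 to 43.8 ± 9.60. Collagen Col3a1 went from 2.19 ± 0.608 to 102 ± 12.0 TPM. In the stromal list 9 of 16 measured members rose and 7 were not called, or 9 rose and 1 fell adjusted over the list alone (adjusted p = 0.16). Midkine rose from 2.06 ± 0.332 to 286 ± 3.68 TPM (log2 change 6.55 ± 1.16, adjusted p = 4.2e-05). The 3591 calls split into 2809 higher and 782 lower, and into 1974 and 1315 relative to a difference in scale of 0.39.

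The Dynll1 knockout of day 13 had the highest count of calls among the knockouts, 5926, with 4642 higher and 1284 lower (3128 and 2061 relative to a difference in scale of 0.58). Padi6 fell from 28907 ± 629 to 134 ± 8.90 TPM (log2 change -7.74 ± 0.12, adjusted p = 9.3e-26) and Zp3 from 16324 ± 139 to 77.2 ± 4.53 TPM (n = 2). Egg coat genes fell (9 of 9 measured members fell; adjusted p = 3.2e-10). Among growing-oocyte transcripts 16 of 17 measured members fell and 1 was not called (adjusted p = 3.7e-17), and in the list of screened factors 9 of 12 measured members fell and 3 were not called (adjusted p = 3.7e-11, or 8 of 11 and adjusted p = 1.3e-09 without Dynll1 itself). Early meiosis genes were higher (13 of 16 measured members rose and 3 were not called, or 10 rose after rescaling; adjusted p = 0.0017, and adjusted p = 0.22 with an estimated correlation). Dmc1 went from 3.98 ± 3.08 to 177 ± 4.71 TPM. Sox2, a factor of pluripotent and early germ cells, was at 96.0 ± 3.10 TPM against 0.120 and 0 in the wild-type libraries. In the pluripotency list 8 of 13 measured members rose, 1 fell and 4 were not called (adjusted p = 0.10). Dnmt3l, a cofactor of DNA methylation, rose from 4.54 ± 1.30 to 72.5 ± 0.332 TPM (log2 change 3.75 ± 0.33, adjusted p = 3.0e-10). Heat shock and immediate early genes were higher (12 of 14 measured members rose and 2 were not called; adjusted p = 0.0010, and adjusted p = 0.16 with an estimated correlation). Jun went from 20.8 ± 0.714 to 488 ± 4.31 TPM. Granulosa markers did not pass as a list (13 of 21 measured members rose, 1 fell and 7 were not called, or 11 rose and 4 fell after rescaling; adjusted p = 0.25), nor did blood and immune markers (5 of 10 measured members rose, 1 fell and 4 were not called; adjusted p = 0.97).

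**Figure D2:**
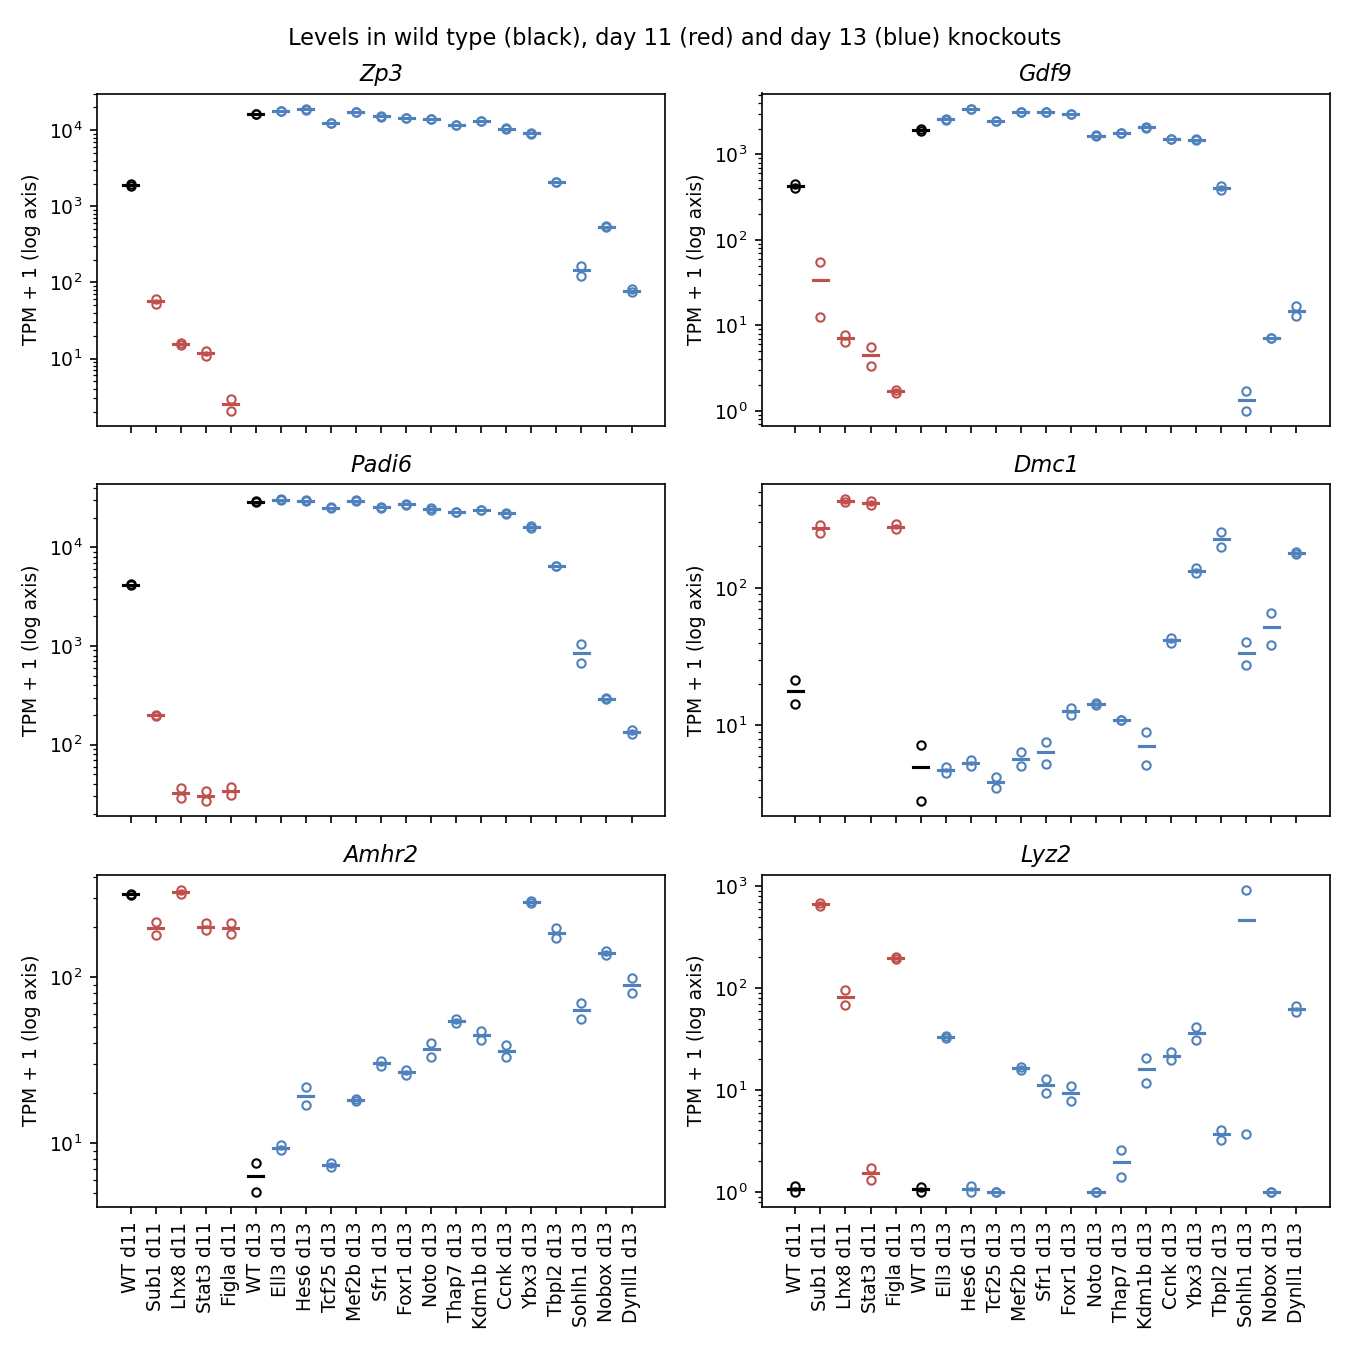
Levels of Zp3, Gdf9 and Padi6 (oocyte growth), Dmc1 (early meiosis), Amhr2 (granulosa) and Lyz2 (macrophage) in wild-type and knockout oocytes of day 11 and day 13, as TPM + 1 on a log axis. Circles are libraries and bars are group means; Zp3 reads 16324 ± 139 TPM in wild type of day 13 and 77.2 ± 4.53 in the Dynll1 knockout.

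Granulosa markers rose in the Ybx3 knockout of day 13, of a Y-box RNA-binding protein (15 of 21 measured members rose and 6 were not called, or 16 rose adjusted over the list alone; adjusted p = 1.9e-08). Amhr2 rose from 5.36 ± 1.77 to 283 ± 6.82 TPM (log2 change 5.51 ± 0.16, adjusted p = 4.6e-19) and Inha from 12.6 ± 1.24 to 593 ± 7.61 TPM (n = 2). Myl9 rose from 1.29 ± 0.707 to 416 ± 37.3 TPM (log2 change 7.54 ± 0.53, adjusted p = 2.7e-11), and Nr4a1, an early-response nuclear receptor, from 3.38 ± 0.530 to 282 ± 21.4 TPM. Immediate early genes were higher (10 of 14 measured members rose and 4 were not called; adjusted p = 1.7e-05, and adjusted p = 0.062 with an estimated correlation). Early meiosis genes rose (11 of 16 measured members rose and 5 were not called; adjusted p = 3.5e-07). Dmc1 went from 3.98 ± 3.08 to 133 ± 7.17 TPM. The growing-oocyte list was lower with few calls (3 of 17 measured members fell and 14 were not called, or 7 fell after rescaling; adjusted p = 1.1e-08). Maternal mRNA storage genes were lower too (1 of 11 measured members fell and 10 were not called; adjusted p = 1.9e-06). Zar1 went from 1495 ± 59.9 to 687 ± 14.0 TPM (adjusted p = 0.085 with a pseudocount of 0.1). Calls numbered 2199, 1927 higher and 272 lower, and 1522 and 608 relative to a difference in scale of 0.30.

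In the libraries labelled Ccnk knockout, Mos, the kinase that holds eggs in meiotic arrest, fell from 155 ± 5.47 to 42.0 ± 0.212 TPM (log2 change -1.86 ± 0.51, adjusted p = 0.012) and Npm2 from 5249.6 ± 70.1 to 2144 ± 80.5 TPM (n = 2). Neither passed with a pseudocount of 0.1 (adjusted p = 0.25 for Mos and adjusted p = 0.059 for Npm2), nor with fewer libraries (adjusted p of 0.060 to 0.072 with any 1 of the 4 libraries left out for Mos, adjusted p of 0.083 to 0.10 with any 1 of the 4 libraries left out for Npm2). The growing-oocyte list was lower (4 of 17 measured members fell and 13 were not called; adjusted p = 1.4e-06). The egg coat list was lower as well (1 of 9 measured members fell and 8 were not called, or 2 fell adjusted over the list alone; adjusted p = 5.3e-06). Early meiosis genes were higher (6 of 16 measured members rose and 10 were not called; adjusted p = 4.3e-05, and adjusted p = 0.11 with an estimated correlation). Dmc1 went from 3.98 ± 3.08 to 40.8 ± 2.47 TPM. Cdkn1a went from 8.80 ± 1.68 to 40.8 ± 3.07 TPM and Amhr2 from 5.36 ± 1.77 to 34.9 ± 4.21, both of the dormancy and PI3K-FOXO list (2 of 12 measured members rose and 10 were not called; adjusted p = 1.6e-04, and adjusted p = 0.052 with an estimated correlation). Amhr2 is a granulosa marker too, and that list did not pass (6 of 21 measured members rose and 15 were not called; adjusted p = 0.065). The 755 calls were 643 higher and 112 lower (382 and 223 relative to a difference in scale of 0.28), and numbered 472 without knockout replicate 1.

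The 9 other knockouts of day 13 called between 14 and 393 genes. In the Kdm1b knockout 374 genes were higher and 19 lower (665 called when the Sohlh1 knockout libraries, whose replicates differ most, were left out of the fit). Granulosa markers rose (11 of 21 measured members rose and 10 were not called; adjusted p = 1.5e-11), with Inha going from 12.6 ± 1.24 to 142 ± 8.10 TPM (log2 change 3.40 ± 0.13, adjusted p = 1.7e-15). Stromal markers were higher (5 of 16 measured members rose and 11 were not called, or 10 rose adjusted over the list alone; adjusted p = 1.2e-06, and adjusted p = 0.10 with an estimated correlation). Col3a1 went from 2.19 ± 0.608 to 61.2 ± 5.20 TPM (n = 2, adjusted p of 0.080 to 0.12 with any 1 of the 4 libraries left out). Jun went from 20.8 ± 0.714 to 199.9 ± 11.5 TPM among immediate early genes (8 of 14 measured members rose and 6 were not called, or 10 rose adjusted over the list alone; adjusted p = 5.0e-09). Hist1h1c, a linker histone, fell from 37.1 ± 1.12 to 13.6 ± 2.12 TPM.

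The Thap7 knockout called 337 genes, 295 higher and 42 lower (271 and 71 relative to a difference in scale of 0.11). Granulosa markers rose (8 of 21 measured members rose and 13 were not called, or 11 rose adjusted over the list alone; adjusted p = 1.7e-08). Amhr2 rose from 5.36 ± 1.77 to 53.3 ± 2.10 TPM (log2 change 3.12 ± 0.16, adjusted p = 5.3e-13) and Myl9 from 1.29 ± 0.707 to 59.3 ± 15.0 TPM (n = 2). Maternal mRNA storage genes were lower as a list with no single call (adjusted p = 9.3e-08). Pabpc1l fell from 139 ± 11.1 to 56.0 ± 1.20 TPM, a call that ended with a pseudocount of 0.1 (adjusted p = 0.39) or with fewer libraries (adjusted p = 0.057 without knockout replicate 1, 0.070 without wild-type replicate 2 and 0.066 without knockout replicate 2). The Noto knockout, of a homeobox factor of the notochord, called 275, 251 higher and 24 lower. Immediate early genes rose there (9 of 14 measured members rose and 5 were not called, or 10 rose adjusted over the list alone; adjusted p = 5.9e-15). Jun went from 20.8 ± 0.714 to 171 ± 4.89 TPM. Granulosa markers rose too (8 of 21 measured members rose and 13 were not called; adjusted p = 9.3e-08). Inha went from 12.6 ± 1.24 to 80.5 ± 5.24 TPM. Aspm, a spindle pole protein, fell from 33.3 ± 1.41 to 14.5 ± 0.177 TPM (log2 change -1.15 ± 0.23, adjusted p = 0.0035). Calls for Thap7 numbered 162 without knockout replicate 1, 205 without wild-type replicate 2 and 162 without knockout replicate 2, and 545 without the Sohlh1 knockout libraries. Calls for Noto numbered 139 without knockout replicate 1, 171 without wild-type replicate 2 and 168 without knockout replicate 2, and 502 without the Sohlh1 knockout libraries.

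In the Foxr1, Mef2b and Sfr1 knockouts Col1a1 and Inha were higher than in wild type. In the Foxr1 knockout, of a forkhead factor, Col1a1 rose from 0.800 ± 0.269 to 26.6 ± 2.06 TPM (log2 change 3.94 ± 0.60, adjusted p = 2.1e-04). Granulosa markers rose (7 of 21 measured members rose and 14 were not called, or 8 rose adjusted over the list alone; adjusted p = 1.8e-08). In the Mef2b knockout Col1a1 went from 0.800 ± 0.269 to 19.0 ± 0.424 TPM and Vim, vimentin, from 19.6 ± 2.79 to 149 ± 6.34 TPM (n = 2, adjusted p of 0.12 to 0.21 with any 1 of the 4 libraries left out). Stromal markers rose (4 of 16 measured members rose and 12 were not called, or 10 rose adjusted over the list alone; adjusted p = 5.0e-09). In the Sfr1 knockout Spp1 was listed at 0 in both wild-type libraries and at 46.9 ± 4.04 TPM in the knockout (adjusted p of 0.17 to 0.22 with any 1 of the 4 libraries left out). Granulosa markers rose (6 of 21 measured members rose and 15 were not called, or 7 rose adjusted over the list alone; adjusted p = 1.2e-06). Inha went from 12.6 ± 1.24 to 75.2 ± 1.12 TPM. Lower calls were few: Cox8c, a cytochrome oxidase subunit, went from 69.8 ± 7.78 to 21.0 ± 3.90 TPM in the Foxr1 knockout (adjusted p of 0.053 to 0.17 with any 1 of the 4 libraries left out). Dnajc19, a mitochondrial import protein, went from 15.0 ± 0.629 to 6.08 ± 0.544 TPM in the Mef2b knockout (adjusted p of 0.14 to 0.30 with any 1 of the 4 libraries left out). The Foxr1 knockout called 231 genes, 227 of them higher, relative to a difference in scale of 0.11, 213 higher and 9 lower. It called 145 without wild-type replicate 1, 112 without knockout replicate 1, 128 without wild-type replicate 2 and 105 without knockout replicate 2, and 482 without the Sohlh1 knockout libraries. For Mef2b 133 were called, 126 of them higher. It called 83 without wild-type replicate 1, 63 without knockout replicate 1, 78 without wild-type replicate 2 and 59 without knockout replicate 2, and 317 without the Sohlh1 knockout libraries. For Sfr1 152 were called, 145 of them higher, relative to a difference in scale of 0.12, 132 higher and 16 lower. It called 93 without wild-type replicate 1, 63 without knockout replicate 1, 97 without wild-type replicate 2 and 77 without knockout replicate 2, and 330 without the Sohlh1 knockout libraries.

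The Hes6 knockout showed higher Socs3, a brake on cytokine signalling, at 3.58 ± 0.0212 to 19.2 ± 1.21 TPM (n = 2, adjusted p of 0.16 to 0.21 with any 1 of the 4 libraries left out). Inha went from 12.6 ± 1.24 to 58.0 ± 0.410. Oog3, an oocyte transcript of a gene family, rose from 11.1 ± 2.44 to 40.1 ± 2.03 TPM (log2 change 1.77 ± 0.37, adjusted p = 0.0058) in a growing-oocyte list that was higher (1 of 17 measured members rose and 16 were not called; adjusted p = 1.3e-04). The Oog3 call ended with a pseudocount of 0.1 (adjusted p = 0.10) and with single libraries left out (adjusted p = 0.11 without wild-type replicate 1, 0.080 without knockout replicate 1 and 0.057 without knockout replicate 2). In the Tcf25 knockout Rn45s, the ribosomal RNA precursor, rose from 86.1 ± 31.0 to 1484 ± 128 TPM (log2 change 4.14 ± 0.15, adjusted p = 1.4e-16). Cxcl1, a chemokine, fell from 14.3 ± 1.45 to 1.65 ± 1.39 TPM. The cholesterol and steroid list was higher, though only Hsd3b1 of 13 measured members rose (adjusted p = 0.0013). In the Ell3 knockout Lyz2 read 32.1 ± 0.827 TPM against 0 and 0.120 in the wild-type libraries (adjusted p of 0.24 to 0.42 with any 1 of the 4 libraries left out, and adjusted p = 0.051 with no filter). Sepp1, a selenium carrier, rose from 4.12 ± 2.55 to 22.0 ± 1.79 TPM. Immediate early genes were higher as a list (0 of 14 measured members were called, or 2 rose adjusted over the list alone; adjusted p = 9.3e-08). Hes6 called 73 genes (65 higher, 8 lower). It called 29 without knockout replicate 1, 47 without wild-type replicate 2 and 37 without knockout replicate 2, and 175 without the Sohlh1 knockout libraries. Tcf25 called 62 (45 higher, 17 lower, and 32 and 33 relative to a difference in scale of 0.16). It called fewer with any 1 of the 4 libraries left out, and 132 without the Sohlh1 knockout libraries. Ell3 called 14 (12 higher, 2 lower). It called 2 without knockout replicate 1 and 3 without knockout replicate 2, and 93 without the Sohlh1 knockout libraries.

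**Figure D3:**
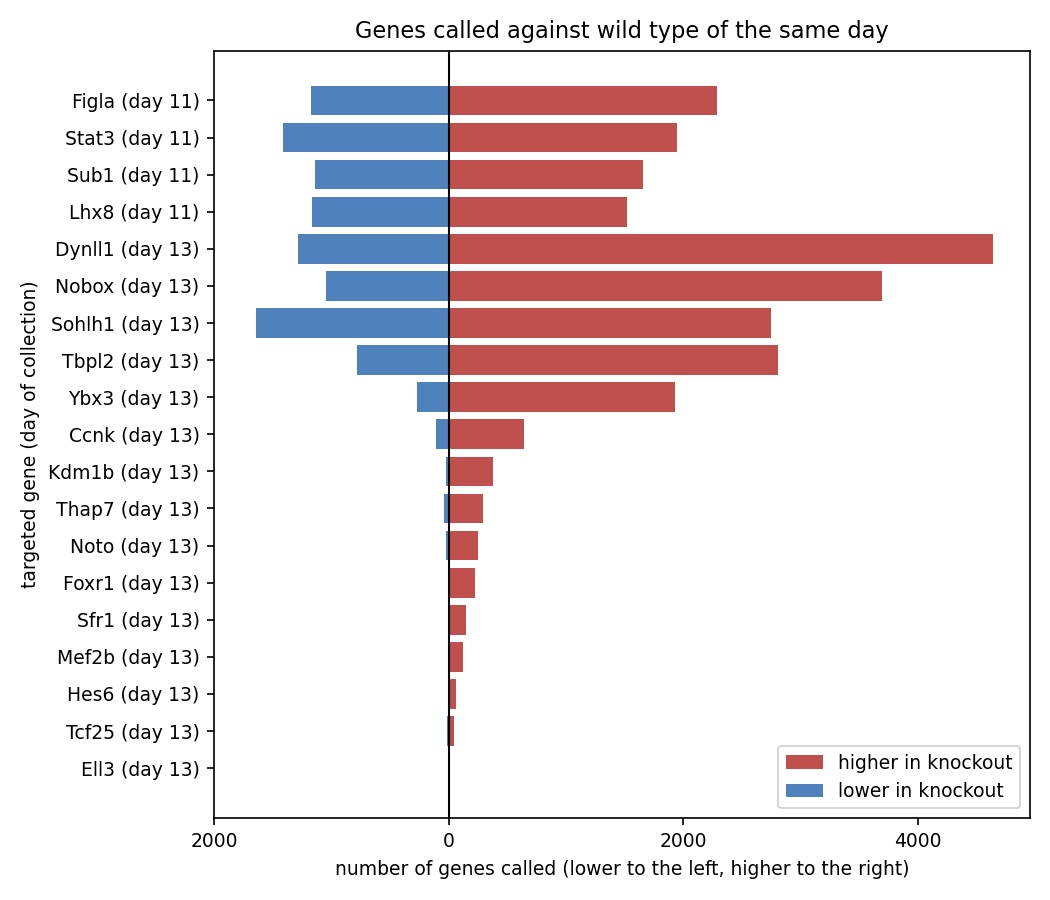
Number of genes called higher (bars to the right) and lower (bars to the left) in each knockout against wild type of the same day. The Dynll1 knockout has 5926 calls and the Ell3 knockout 14.

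Overlap of lower genes was counted for 4 pairs of knockouts named before the data were examined. Figla and Lhx8 shared 715 lower genes, Zp3, Padi6 and Tbpl2 among them, where independent lists of all 12306 genes would share 111. Nobox and Sohlh1 shared 758 against 139.7, with Npm2, Gdf9 and Zar1 among them. Nobox and Tbpl2 shared 581 against 66.5, and Sohlh1 and Tbpl2 597 against 104. Each pair shares its wild-type libraries (n = 2, too few to divide), so part of each excess may come from them. Unchanged groups, simulated so in 20 draws, shared at most 5, which cannot bound that part.

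DIOLs.S were followed from day 1 to day 14 of induction. By day 7 Padi6 rose from 116 ± 20.6 to 14986 ± 2657 TPM (log2 change 7.01 ± 0.13, adjusted p = 5.3e-19), Zp1 from 8.57 ± 0.601 to 1202 ± 212 TPM and Astl, the egg protease that hardens the zona, from 0.245 ± 0.233 to 278 ± 35.3 TPM (n = 2). Growing-oocyte transcripts rose (16 of 17 measured members rose and 1 was not called; adjusted p = 2.6e-11). Egg coat genes rose (8 of 9 measured members rose and 1 was not called; adjusted p = 4.5e-08), and genes of piRNA production too (9 of 16 measured members rose and 7 were not called; adjusted p = 7.5e-05, and adjusted p = 0.12 with an estimated correlation). Tdrd5 went from 11.4 ± 1.48 to 204 ± 40.9 TPM. Pluripotency genes fell (10 of 13 measured members fell and 3 were not called; adjusted p = 7.9e-08): Sox2 was at 98.4 ± 2.21 TPM on day 1 and at 0 and 0.0700 in the libraries of day 7. Esrrb, a nuclear receptor of stem cells, fell from 95.1 ± 2.05 to 2.21 ± 0.912 TPM (log2 change -4.94 ± 0.22, adjusted p = 1.4e-13). Cell cycle genes fell (13 of 18 measured members fell and 5 were not called; adjusted p = 2.2e-07). Top2a went from 539.7 ± 53.5 to 56.1 ± 14.6 TPM. Glycolysis genes fell as well (1 of 11 measured members rose and 10 fell; adjusted p = 6.4e-06). The enolase gene Eno1 went from 1615 ± 52.8 to 51.5 ± 8.83 TPM. The replicates of day 7 differed in some somatic genes: Inha read 1025 and 224 TPM, Col1a1 32.5 and 6.62 and Lyz2 12.7 and 0. These were picked after their values were seen, and the marker lists were not compared between the replicates. Of 3791 called genes 1995 were higher and 1796 lower (1583 and 2089 relative to a difference in scale of 0.19).

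By day 14 Gdf9 rose from 15.2 ± 3.06 to 5869 ± 259.7 TPM (log2 change 8.51 ± 0.17, adjusted p = 3.0e-19) over day 1, Zar1 from 3.06 ± 2.69 to 4235 ± 89.9 TPM and Padi6 from 116 ± 20.6 to 35425 ± 333 TPM (n = 2). Zp3 averaged 187 ± 3.46, 598 ± 63.4, 1069 ± 145, 4837 ± 832 and 27026 ± 1605 TPM on days 1, 3, 5, 7 and 14. Sycp3, of the meiotic chromosome axis, was highest on day 5, at 2023 ± 2.83 TPM, between 403 ± 12.2 on day 1 and 253 ± 0.905 on day 14. In the growing-oocyte list 17 of 17 measured members rose (adjusted p = 1.2e-14). In the egg coat list 9 of 9 measured members rose (adjusted p = 5.3e-10). Screened factors were higher (7 of 12 measured members rose, 1 fell and 4 were not called; adjusted p = 8.8e-05). Kdm1b went from 56.2 ± 6.39 to 630.5 ± 41.5 TPM. Genes of the p53 list fell (1 of 16 measured members rose, 13 fell and 2 were not called; adjusted p = 0.0062, and adjusted p = 0.18 with an estimated correlation). Cdkn1a went from 145 ± 3.96 to 11.1 ± 7.09 TPM. Igfbp2, which binds insulin-like growth factors, fell from 989 ± 29.0 to 0.680 ± 0.325 TPM (log2 change -9.22 ± 0.29, adjusted p = 5.1e-16). The 6188 calls were 1952 higher and 4236 lower (2283 and 3857 relative to a difference in scale of -0.21).

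**Figure D4:**
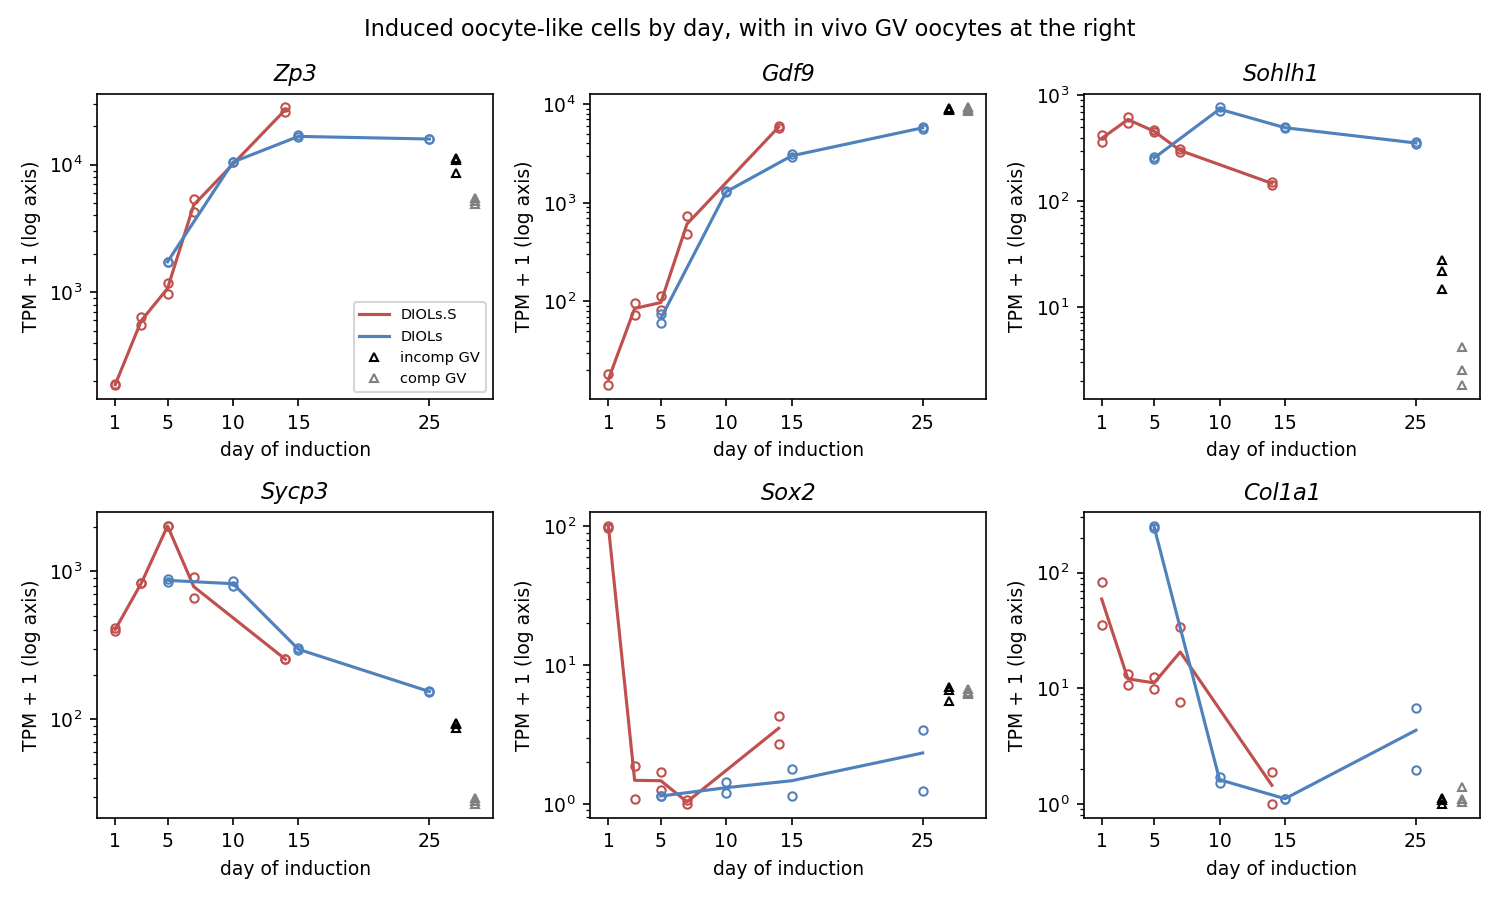
Levels of oocyte, meiotic, stem cell and stromal genes in DIOLs.S and DIOLs by day of induction, and in GV oocytes, as TPM + 1 on a log axis. Lines join group means, circles are libraries and triangles are GV oocytes; Zp3 reaches 27026 ± 1605 TPM in DIOLs.S of day 14.

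DIOLs of day 25, grown on collagen-coated membranes, were compared with DIOLs of day 5. Gdf9 rose from 66.3 ± 9.08 to 5760.2 ± 232 TPM (log2 change 6.42 ± 0.17, adjusted p = 1.8e-16), Oog4 from 2.88 ± 0.771 to 393 ± 9.39 TPM and Eif4e1b, an oocyte cap-binding protein, from 20.8 ± 2.98 to 1602 ± 12.1 TPM (n = 2). Egg coat genes rose (9 of 9 measured members rose; adjusted p = 8.7e-11). Among growing-oocyte transcripts 14 of 17 measured members rose and 3 were not called (adjusted p = 1.7e-14). Kit went from 55.8 ± 1.61 to 406 ± 10.3 TPM and Dnmt3l from 1.06 ± 0.750 to 26.9 ± 2.29. Stromal markers did not pass (2 of 14 measured members rose, 8 fell and 4 were not called; adjusted p = 0.62). Col1a1 fell from 248 ± 5.82 to 3.33 ± 3.36 TPM (log2 change -6.10 ± 0.55, adjusted p = 6.4e-09) and Fabp4, a fatty acid carrier, from 467 ± 5.58 to 1.76 ± 0.156 TPM. Early meiosis genes did not pass either (9 of 16 measured members fell and 7 were not called, or 6 fell after rescaling; adjusted p = 0.063), Sycp3 going from 867 ± 32.2 to 153 ± 0.191 TPM. In the cell cycle list 6 of 18 measured members rose, 4 fell and 8 were not called (adjusted p = 0.0076, and adjusted p = 0.21 with an estimated correlation). Birc5, a spindle protein, went from 117 ± 6.31 to 483 ± 1.61 TPM. Calls numbered 5144, 1269 higher and 3875 lower, and 1683 and 2892 relative to a difference in scale of -0.33.

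At day 5, DIOLs.S and DIOLs differed in 1378 genes, 520 higher in DIOLs.S and 858 lower (560 and 609 relative to a difference in scale of -0.12). Early meiosis genes were higher in DIOLs.S (10 of 16 measured members were higher and 6 were not called; adjusted p = 1.8e-08). Rec8 was at 53.7 ± 6.77 TPM v 14.8 ± 0.311 (adjusted p = 0.088 with 1 fit over all samples) and Prdm9 at 47.3 ± 2.62 TPM v 12.3 ± 0.912 (n = 2). Granulosa markers were higher (11 of 21 measured members were higher, 2 were lower and 8 were not called; adjusted p = 4.2e-04, and adjusted p = 0.41 with an estimated correlation). Inha was at 149 ± 10.9 TPM v 2.89 ± 0.693 and Wt1, a factor of gonadal somatic cells, at 27.7 ± 1.07 TPM v 0.625 ± 0.403. Spp1 was lower, at 1.05 ± 0.438 TPM v 589.9 ± 22.3, and Col1a1 at 10.1 ± 1.92 TPM v 248 ± 5.82. The stromal list did not pass (6 of 14 measured members were lower and 8 were not called; adjusted p = 0.18).

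Competent GV oocytes were compared with incompetent ones (n = 3 each) to ask what changes as oocytes gain the ability to develop. The columns matched to them are named for 3 weeks (competent) and 2 weeks (incompetent), ages that the labels do not give, so age and competence differ together. Sohlh1 was lower from 20.6 ± 6.69 to 1.84 ± 1.21 TPM (log2 change -2.96 ± 0.22, adjusted p = 1.5e-09), Kdm1b from 566 ± 85.7 to 155 ± 9.22 TPM and Zfp707, a zinc finger gene, from 282 ± 22.1 to 19.4 ± 4.21 TPM. Screened factors were lower (4 of 12 measured members were lower and 8 were not called; adjusted p = 3.8e-05). Genes of piRNA production were lower (4 of 16 measured members were lower and 12 were not called; adjusted p = 4.4e-04, and adjusted p = 0.16 with an estimated correlation). Piwil2 went from 33.1 ± 7.55 to 3.43 ± 0.397 TPM and Ddx4, a germ cell helicase, from 237 ± 18.4 to 58.9 ± 3.78. Early meiosis genes were lower too (4 of 16 measured members were lower and 12 were not called; adjusted p = 0.011, and adjusted p = 0.12 with an estimated correlation). Sycp3 went from 90.5 ± 3.91 to 27.1 ± 1.36 TPM. Higher genes included Axin2, a brake on Wnt signalling, which went from 71.6 ± 7.03 to 270.3 ± 18.3 TPM (log2 change 1.90 ± 0.12, adjusted p = 2.3e-10), and Dusp1, a phosphatase, from 30.8 ± 4.25 to 121 ± 12.3 TPM. Fos went from 1.45 ± 0.193 to 28.9 ± 19.0 TPM and Inha from 12.2 ± 0.780 to 45.5 ± 23.2 (adjusted p = 0.10 without competent replicate 2, 0.080 without competent replicate 3 and 0.054 without incompetent replicate 3). Neither the immediate early list (3 of 14 measured members were higher, 2 were lower and 9 were not called; adjusted p = 0.21) nor the granulosa list (5 of 21 measured members were higher, 1 was lower and 15 were not called; adjusted p = 0.30) passed. In all 1156 genes were called, 295 higher and 861 lower.

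DIOLs of day 25 (n = 2) were set against incompetent GV oocytes (n = 3). Sohlh1 stood at 354 ± 11.2 TPM v 20.6 ± 6.69 in GV oocytes and Tbpl2 at 153 ± 11.6 TPM v 60.8 ± 11.5. The list of screened factors was higher (4 of 12 measured members were higher and 8 were not called; adjusted p = 0.0030, and adjusted p = 0.13 with an estimated correlation). Growing-oocyte transcripts were lower (4 of 17 measured members were lower and 13 were not called; adjusted p = 0.0014, and adjusted p = 0.31 with an estimated correlation). Oog4 was at 393 ± 9.39 TPM v 1244 ± 90.0 and the connexin gene Gja4 at 577 ± 5.11 TPM v 1395 ± 26.3. Dnmt3l was lower, at 26.9 ± 2.29 TPM v 258 ± 17.4 (log2 change -3.21 ± 0.20), and Gpr3, a receptor that keeps oocytes arrested, at 11.9 ± 4.04 TPM v 170.1 ± 1.52. Genes of cholesterol synthesis were higher (6 of 13 measured members were higher, 1 was lower and 6 were not called; adjusted p = 0.0076, and adjusted p = 0.29 with an estimated correlation). Genes of the p53 list were higher too (7 of 16 measured members were higher and 9 were not called; adjusted p = 0.033, and adjusted p = 0.29 with an estimated correlation). Ccng1 was at 56.2 ± 6.34 TPM v 8.42 ± 0.873. Zp3 read 15911 ± 195 TPM in these DIOLs and 10322 ± 1451 in incompetent GV oocytes, and Gdf9 5760.2 ± 232 and 8925 ± 164. Genes with copies stood out here too, Hmgn2 at 115 ± 12.0 TPM v 4.79 ± 0.709 and Atp5g2 at 89.2 ± 15.0 TPM v 1.08 ± 0.605. No library set holds both kinds of cell, so set and cell type cannot be told apart. Calls numbered 3051, 1483 higher and 1568 lower in DIOLs.

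DIOLs matured to metaphase II (n = 2) were set against competent GV oocytes (n = 3), an earlier stage. Origin and library set differed too, and RNA amount was not separated from polyA selection. Padi6 was lower, at 12.2 ± 2.24 TPM v 5661 ± 143, and Zp3 at 258 ± 5.73 TPM v 5184 ± 262. Cdk1 was at 2.83 ± 1.32 TPM v 110.3 ± 4.08. Genes of piRNA production were lower (adjusted p = 0.0076, or 0.28 with an estimated correlation). Of 16 measured members 2 were higher, 10 lower and 4 not called. Tdrd1 was at 15.0 ± 1.11 TPM v 297 ± 3.10. Cholesterol and steroid genes were higher (adjusted p = 5.0e-04, or 0.17 with an estimated correlation). Of 13 measured members 9 were higher, 1 lower and 3 not called. Hmgcs1 was at 1062 ± 4.45 TPM v 118 ± 0.221. Ccnb1, cyclin B, was higher, at 1468 ± 44.5 TPM v 248 ± 4.33, and Sycp3 at 510.2 ± 15.2 TPM v 27.1 ± 1.36. Vim was at 68.6 ± 10.0 TPM v 0.807 ± 0.333. The granulosa list did not pass (9 of 21 measured members were higher, 2 lower and 10 not called, or 8 and 2 adjusted over the list alone, or 12 and 1 after rescaling, adjusted p = 0.098). Of 5821 calls 2119 were higher and 3702 lower, and 3573 and 2816 relative to a difference in scale of -0.79.

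Similarity of DIOLs to GV oocytes was measured as a correlation across 12689 genes, which are not independent replicates. Against incompetent GV oocytes DIOLs.S went from r = 0.669 on day 1 to 0.919 on day 14, and DIOLs from 0.764 on day 5 to 0.934 on day 25. Against competent GV oocytes day 25 gave 0.898, and the matured DIOLs gave 0.806. Both kinds of GV oocyte correlated at 0.977. Kit read 406 ± 10.3 TPM in DIOLs of day 25 and 273 ± 30.7 in incompetent GV oocytes, Ddx4 218 ± 5.17 and 237 ± 18.4, and Pou5f1 519 ± 10.2 and 435 ± 16.6.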

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

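Of the tests in this part, those of shared wild-type libraries, of a delay by counts of calls in the Tbpl2, Nobox, Sohlh1 and Dynll1 knockouts and of the splits of GV oocytes were set out before their results were seen; the tests of scaling, cell types, a delay by lists or in 9 further knockouts, other controls, sequence copies, labels and direct differences between knockouts came after.

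In 9 knockouts of day 13 with at least 50 calls (Hes6, Thap7, Ybx3, Foxr1, Mef2b, Sfr1, Kdm1b, Noto and the libraries labelled Ccnk), at least 80% of the calls were higher, granulosa genes such as Inha among them. A difference in scaling between libraries is argued against, since after rescaling 8 of the 9 still had at least 70% higher calls (range 63.1 to 95.9%). A delay as far as wild type of day 11 is argued against in 8 of the 9. These had 1516 (labelled Ccnk) to 3094 (Hes6) calls against day 11, more than against day 13. It stays open in the Ybx3 knockout, with 777 and 2199 calls (35.3%) and 245 of its 1927 higher calls also higher against day 11. RNA of granulosa or other gonadal somatic cells in the knockout libraries stays open, although the sort for Stella-CFP would remove such cells: with an estimated correlation the granulosa list was higher in 8 of the 9, the immediate early and heat shock list in 6, the stromal list in 1 and the immune list in 0, and of 21 granulosa markers 6 were at 10 TPM or more in GV oocytes and 2 stood in another list. Stress in handling, which would raise immediate early genes, stays open as untested. Low values of the 2 shared wild-type libraries stay open. With Tcf25 and with Ell3 libraries of day 13 as controls, 7 of the 9 kept at least 50 calls, at least 80% higher. Hes6 and Mef2b did not. Both controls are near wild type (62 and 14 calls), so the test cannot decide. A median of 66.9% of a knockout's higher calls were called higher in at least 5 of the 9. A shared effect of the losses would give this as well. An effect of the lost genes and a smaller delay stay open as untested. Wild type had 2707 calls between the days, with 187 of the 189 genes so shared lower on day 13. Less somatic RNA could give this too.

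The Figla and Sohlh1 knockout libraries stood apart from the other in vitro libraries in genes with copies: Hmgn2 read 289 and 215 TPM there and 5.33 to 17.3 in the other 19 groups, but also 115 to 735 in the 9 groups of DIOLs before maturation, which are not labelled as knockouts (15.6 in matured DIOLs). Reads shared with copies of a gene and counted differently in these libraries may be the cause, since genes of shared sequence stood at least 0.48 (log2) above genes without in both, against -0.21 to 0.050 in the 17 other knockouts. A mislabelled sample from the other 19 in vitro groups is argued against, as Sohlh1 read at most 27.3 TPM in the 4 Figla and Sohlh1 knockout libraries and at least 148 in the 38 others. An exchange between the Figla and Sohlh1 libraries or with a sample from elsewhere was not tested. RNA of blood, immune or stromal cells in replicate 2 of the Sohlh1 knockout stays open despite the sort. Of 18 markers at 10 TPM or more in either replicate, a filter favouring gaps, 14 were at least 4 times higher in replicate 2. Of 10 immune and 16 stromal markers 1 and 2 reached 10 TPM in GV oocytes. Genes with copies read high in DIOLs without loss of Figla or Sohlh1, in cells of another kind. No wild-type in vitro library reads them so. An effect of either loss on them was not tested.

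Oocyte growth genes were lower in the Tbpl2, Nobox, Sohlh1 and Dynll1 knockouts of day 13, with early meiosis genes called higher in each. As a list the latter passed with an estimated correlation in the Tbpl2 knockout alone (adjusted p = 0.036), with the preset one alone in Nobox (estimated 0.18) and Dynll1 (0.22), and with neither in Sohlh1 (preset 0.10). A difference in scaling between libraries is argued against, as 9 of 9 egg coat genes were lower after rescaling in each of the 4. Oocyte RNA diluted by RNA of other cells is argued against as the whole cause in the Tbpl2, Nobox and Dynll1 knockouts, where 12 to 13 of 16 early meiosis genes, of germ cells, were called higher and 0 lower (8 to 11 higher after rescaling). It is argued against in the Sohlh1 knockout too: of 9 such genes at 10 TPM or more in wild type the lowest log2 change was -0.60 ± 0.16, while the 9 egg coat genes changed by -10.54 to -2.62. A delay, so that day 13 knockouts are near wild type of day 11, was not decided by counts of calls. Day 11 controls gave 32.7% as many as day 13 for Tbpl2, 49.7% for Nobox, 64.5% for Dynll1 and 72.1% for Sohlh1. Egg coat genes argue against a delay in the Nobox (6 of 9 called lower than on day 11), Sohlh1 and Dynll1 knockouts (7 each). Early meiosis genes do so in the Tbpl2 knockout (9 of 16 higher, with 9 in Dynll1 and 6 in Nobox). A delay stays open for egg coat genes in Tbpl2 (0 lower) and early meiosis genes in Sohlh1 (2 higher, 2 lower). A stop before day 11 was not tested. An effect of each lost gene on the passage from meiosis to growth stays open as untested.

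Competent and incompetent GV oocytes differed in 1156 genes, and the highest count among the other 9 of the 10 splits of the 6 libraries was 0, so 1 split gave as many and no share under 0.1 can be reached with so few splits. The columns matched to these groups are named for 3 and 2 weeks of age, so an effect of age stays open as untested.

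Direct comparisons between knockouts, tested by limma, gave genes called in opposite directions against wild type whose difference was itself called, and the examples were chosen after their values were seen. Figla and Lhx8 differed so in 13 genes. Nobox and Sohlh1 differed so in 135, with Bmp7, a growth factor, at 139 and 0.605 TPM against 9.28 in wild type (difference 6.56 ± 0.24, adjusted p = 1.8e-17). Nobox and Tbpl2 differed so in 19, with the keratin gene Krt79 at 353 and 30.3 TPM against 66.8 in wild type (difference 3.50 ± 0.36, adjusted p = 2.9e-08). Sohlh1 and Tbpl2 differed so in 80, with Dmrt1 at 0.705 and 109 TPM against 8.94 in wild type (difference -6.15 ± 0.32, adjusted p = 2.6e-14). The 2 highest counts involve the Sohlh1 libraries, whose copied genes and replicate 2 stand apart as above, so a difference between the lost genes was not separated from these. Genes of shared sequence made up 11 of the 135 and 3 of the 80.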

How the results depend on the processing

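Fits without the Sohlh1 knockout libraries and without genes of shared sequence were chosen after seeing the data. All 27 counts of called genes stayed within 1.5 times of the main one with no filter, with TPM rescaled by the median of ratios, without genes of shared sequence and with the replicate number as a block. Of 201 tests of genes named beside a comparison, 201 kept direction and side of the threshold with the replicate block, 200 with no filter, 199 after rescaling, 199 with 1 fit over all samples and 194 with a pseudocount of 0.1, and 129 of 130 without the Sohlh1 knockout libraries, 179 of 179 without genes of shared sequence and 795 of 843 with 1 library left out. The sign of Ccnk in the libraries labelled Ccnk knockout, not called in any fit, turned after rescaling (log2 change -0.26) and without wild-type replicate 1 (-0.014) or knockout replicate 1 (-0.042) but not without knockout replicate 2 (0.082), and the cause was not tested. The labels do not say that equal replicate numbers share a culture, and deviations of equal numbers correlated at -0.032 to 0.062 over 210 pairs of in vitro groups and at -0.15 to 0.28 over 66 pairs of DIOL and GV groups. The replicate block gave 1156 called genes for GV oocytes against 1156, 76 for Hes6 against 73, and 186 passing list tests against 184.

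A pseudocount of 0.1 called 146 genes for Hes6, 36 for Ell3, 387 for Foxr1, 218 for Mef2b, 271 for Sfr1 and 133 for Tcf25; the cause was not tested. With 1 fit over all samples Tcf25 called 98; the cause was not tested. Leaving out the Sohlh1 knockout libraries, whose spread enters every in vitro test, raised the counts to 175 for Hes6, 545 for Thap7, 93 for Ell3, 482 for Foxr1, 317 for Mef2b, 330 for Sfr1, 132 for Tcf25, 665 for Kdm1b and 502 for Noto. With an estimated correlation 115 list tests passed, and 201 after rescaling. Without the fold threshold 1372 lower genes were shared by Figla and Lhx8, 1184 by Nobox and Sohlh1, 1054 by Nobox and Tbpl2 and 1069 by Sohlh1 and Tbpl2, as more genes are called.

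Leaving out 1 library, with a lone sample assumed to vary like the other groups, lowered counts by over 1.5 times in 9 comparisons, where fewer samples were fitted. The Hes6 knockout gave 29 without knockout replicate 1, 47 without wild-type replicate 2 and 37 without knockout replicate 2, with a range of 29 to 56. The Thap7 knockout gave 162 without knockout replicate 1, 205 without wild-type replicate 2 and 162 without knockout replicate 2, with a range of 162 to 231. The Ell3 knockout gave 2 without knockout replicate 1 and 3 without knockout replicate 2, with a range of 2 to 11. The Foxr1 knockout gave 145 without wild-type replicate 1, 112 without knockout replicate 1, 128 without wild-type replicate 2 and 105 without knockout replicate 2, with a range of 105 to 145. The Mef2b knockout gave 83 without wild-type replicate 1, 63 without knockout replicate 1, 78 without wild-type replicate 2 and 59 without knockout replicate 2, with a range of 59 to 83. The libraries labelled Ccnk knockout gave 472 without knockout replicate 1, with a range of 472 to 567. The Sfr1 knockout gave 93 without wild-type replicate 1, 63 without knockout replicate 1, 97 without wild-type replicate 2 and 77 without knockout replicate 2, with a range of 63 to 97. The Tcf25 knockout gave 32 without wild-type replicate 1, 34 without wild-type replicate 2 and 30 without knockout replicate 2, with a range of 30 to 53. The Noto knockout gave 139 without knockout replicate 1, 171 without wild-type replicate 2 and 168 without knockout replicate 2, with a range of 139 to 187. In the other 18 comparisons each count stayed within 1.5 times.

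Across the 9611 genes with TPM of at least 10 in at least 2 libraries similarity to incompetent GV oocytes was 0.492, 0.596, 0.643, 0.706 and 0.885 for DIOLs.S of days 1, 3, 5, 7 and 14, 0.636, 0.805, 0.855 and 0.907 for DIOLs of days 5, 10, 15 and 25, and 0.690 for matured DIOLs. To competent GV oocytes it was 0.463, 0.557, 0.595, 0.656 and 0.828 for DIOLs.S of days 1, 3, 5, 7 and 14, 0.588, 0.743, 0.794 and 0.856 for DIOLs of days 5, 10, 15 and 25, and 0.736 for matured DIOLs. Both kinds of GV oocyte correlated at 0.968. Depth is unknown, so what it limits cannot be stated.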

Other observations

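Trp63, a p53 family member of the oocyte, fell from 87.4 ± 11.6 to 2.31 ± 0.219 TPM (log2 change -4.74 ± 0.18, adjusted p = 3.0e-17) in the Lhx8 knockout (n = 2), from 87.4 ± 11.6 to 1.00 ± 0.658 TPM in the Stat3 knockout and from 99.8 ± 4.44 to 3.31 ± 0.431 in the Dynll1 knockout. Perp, a target of p53 family proteins, fell from 79.8 ± 12.9 to 8.05 ± 2.86 TPM in the Lhx8 knockout and from 79.8 ± 12.9 to 7.38 ± 5.49 in the libraries labelled Sub1 knockout. Top2a rose from 43.5 ± 7.03 to 343 ± 10.6 TPM without Lhx8 and from 9.52 ± 0.884 to 420.0 ± 14.1 without Dynll1, while Uhrf1, a partner of DNA methylation upkeep, fell from 325 ± 0.276 to 59.4 ± 5.85 and from 881 ± 26.4 to 96.9 ± 2.06 TPM. Car9, a carbonic anhydrase of the hypoxia response, rose from 13.7 ± 1.76 to 89.9 ± 7.85 TPM between wild type of day 11 and day 13. It fell from 89.9 ± 7.85 to 4.00 ± 2.45 TPM in the Nobox knockout.

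In DIOLs.S Sohlh1 averaged 392 ± 43.7, 591 ± 53.2, 457 ± 16.3, 300.4 ± 16.3 and 146 ± 6.70 TPM on days 1, 3, 5, 7 and 14 (n = 2 each), and Kdm1b 56.2 ± 6.39, 228 ± 32.2, 359 ± 8.76, 553 ± 104 and 630.5 ± 41.5. In DIOLs Gdf9 averaged 66.3 ± 9.08, 1295 ± 17.1, 2996 ± 162 and 5760.2 ± 232 TPM on days 5, 10, 15 and 25.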
